A study of Mus musculus with 12 samples.

How the data were processed

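The data are 12 ChIP-seq libraries of mouse CD4 T cells, with 1 library for each combination of 2 genotypes (wild-type and NLRP3 knockout) with 6 preparations (antibodies to STAT6, NLRP3, IRF4 and BATF, a nonspecific Ig, and input). Per the labels' protocols, naive CD4 T cells were activated on CD3 and CD28 coated plates with IL-4 at 10 ng/ml and an antibody against interferon gamma for some hours. Chromatin of 300000 cells was crosslinked and sheared, immunoprecipitated with a commercial kit, made into NEBNext Ultra libraries and sequenced on a MiSeq. The cells came from mice 7 weeks old. Groups were taken from the sample titles.

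Each library has 1 deposited list of peaks, called with MACS in Galaxy per the file headers. The version of MACS, its cut-off, and the library it used as control are not given in the sources used here. Per the submitters' processing notes the reads were aligned with Bowtie2. Each deposited peak has a start, an end and a score from the authors' caller. No score was below 50, and the score was read as 10 times the negative log10 of the peak's p, as MACS 1 writes it. It is the peak's own value and was not normalized between libraries. It was used to rank the peaks of a list and, as a common minimum, to filter all lists, and counts past such a minimum carry differences in depth and control as well. The lists give no read counts, so the depth of each library is unknown, and a list can be longer or shorter because of depth or of the control used by the caller. A score in 1 list cannot be turned into an occupancy relative to another list.

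The submitters' processing notes name the build mm8. The peak positions contradict that build. They reach 152397321 on chromosome 7, 152493651 on chromosome 5 and 197127924 on chromosome 1, past the known ends of these chromosomes in mm8 and within those in mm9. On 10 of 21 chromosomes they also run past the last gene of GRCm38. Coordinates are printed as deposited, counted from 1, and are most probably mm9. No genome or annotation of that build was used here, so genes, exons and promoters near the peaks, the fixed lists of Th2 and other genes, and sequence motifs were not analysed here.

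Overlaps between lists were counted with bedtools 2.31.1 as the number of peaks of a list that share at least 1 bp with a peak of another list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the rest. Shares have exact Clopper-Pearson 95% intervals, and ratios of peak counts have intervals from the same method applied to the share of the total. These cover counting error only. Neighbouring peaks and reads without molecular identifiers are not independent. Each share was set beside 1000 random placements of the peaks within their chromosomes, between the first and last position of any list. On short unplaced sequences some placements can hardly miss a peak, so the placement values for NLRP3 peaks in STAT6, IRF4 and BATF are given for chromosomes 1 to 19, X and Y alone, a choice made after the data were seen. The ratios to placement for NLRP3 and Ig peaks in IRF4 are given with and without these sequences. With 1 library per group no test between groups was made and no p-value was computed. The overlap and placement code was tested on simulated lists shaped like wild-type NLRP3 and IRF4, wild-type and knockout STAT6, and wild-type and knockout BATF. In each case 100 of 100 planted shared peaks were found. Planted peaks were centred on a target peak, so this checks the code only. Other overlaps numbered 0, 1 and 5 in that order, where placement gave 0.06, 0.16 and 2.51. The simulated lists lay on chromosomes 1 to 19, X and Y and held no background regions common to the libraries.

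Control-free peaks overlap no Ig or input peak of their genotype. The rule for the regions named was fixed before the data were examined. It takes, on chromosomes 1 to 19, X and Y, the 5 highest-scored peaks of each antibody and genotype that overlap no Ig or input peak of either genotype, the 5 highest present in both genotypes, the 5 highest wild-type NLRP3 peaks that meet a factor peak, and the 3 regions in the most lists. Ties were settled by position. A further part of the rule, on genes of fixed lists, was void without an annotation. From these the text gives those that lead each comparison. Alternatives fixed before the data were examined were a minimum score of 100, an overlap of 50% of the shorter peak, a distance of up to 1000 bp, chromosomes 1 to 19, X and Y only, merging of peaks within 1000 bp, removal of peaks in Ig or input, and circular shifts in place of random placement. Minimum scores of 80 and 200 for the count ratios, the score classes, the equal filtering of NLRP3 and Ig, and the shares of peaks with a score of at least 100 found in other lists were added after the data were seen.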

Results

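Chromatin immunoprecipitation and sequencing (ChIP-seq) recovers the DNA fragments that an antibody pulls down with a crosslinked protein. It was applied here to CD4 T cells of wild-type and NLRP3-knockout C57BL/6 mice that had been placed under Th2 conditions, with IL-4 at 10 ng/ml and an antibody that blocks interferon gamma. Antibodies to 4 proteins were used in each genotype. STAT6 is the transcription factor activated by the IL-4 receptor, IRF4 is an interferon regulatory factor, BATF is an AP-1 family factor that can bind DNA together with IRF4, and NLRP3 is best known as an inflammasome sensor. A nonspecific immunoglobulin (Ig) and an input library without antibody served as background in each genotype. The series asks where NLRP3 and the transcription factors meet on chromatin early in Th2 differentiation. Each of the 12 groups held 1 library, so no difference between genotypes or antibodies can be tested against replicate error. The intervals below are exact Clopper-Pearson 95% intervals that cover counting error of peaks only. The deposited data were MACS peak lists, in which each peak carries the authors' own score, so the read depth behind a peak is unknown.

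The NLRP3 antibody gave 611 peaks in wild-type cells and 661 peaks in cells labelled as NLRP3 knockout. These lists are the most direct check of the knockout label. The number of NLRP3 peaks was not lower in the knockout, at 1.08 times the wild-type number (interval 0.968 to 1.21), so it does not show the loss of the protein. Among peaks with a score of at least 100 the order turned, with 152 wild-type and 93 knockout NLRP3 peaks. Without Ig and input peaks of the same genotype the wild-type and knockout numbers were 433 and 527 over all scores. At scores of at least 100 they were then 25 and 7. The STAT6 list held 3102 peaks in wild-type and 361 in knockout cells, so the wild-type number was 8.59 times the knockout one (7.70 to 9.61). The IRF4 lists held 824 and 1008 peaks. The BATF list held 772 peaks in wild-type and 60926 in knockout cells. The Ig lists held 689 wild-type and 413 knockout peaks, and the input lists held 454 wild-type and 30165 knockout peaks.

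The long knockout lists were made of narrow peaks near the lowest scores. In the knockout BATF list 53548 peaks, or 87.9% (87.6 to 88.1), had the same score of 56.67, and the median width was 58 bp against 103 bp in wild-type BATF. The knockout input list had 86.4% (86.0 to 86.8) of its peaks at 57.35 and a median width of 56 bp. With a minimum score of 100 the knockout BATF list kept 54 peaks and the wild-type BATF list 170, so the direction of the BATF comparison reversed. The input lists kept 9 knockout and 27 wild-type peaks. The STAT6 lists kept 196 wild-type and 129 knockout peaks, a ratio of 1.52 (1.21 to 1.91) in place of 8.59. Without Ig and input peaks the STAT6 ratio was 14.4 (12.4 to 16.6) over all scores and 3.25 (1.94 to 5.67) for scores of at least 100. A higher wild-type number at such scores was not particular to STAT6. The same ratio was 3.57 (1.502 to 9.78) for NLRP3 and 21.75 (8.197 to 81.61) for BATF. For IRF4 it went the other way, at 0.581 (0.402 to 0.833). With Ig and input peaks included, the IRF4 lists kept 195 and 203 peaks at a minimum score of 100 and the Ig lists 101 and 85. At a minimum score of 80 the knockout BATF list was still the longer, with 468 against 253 peaks. Scores depend on read depth and on the caller's control, so counts past a common score do not measure binding either.

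**Figure D1:**
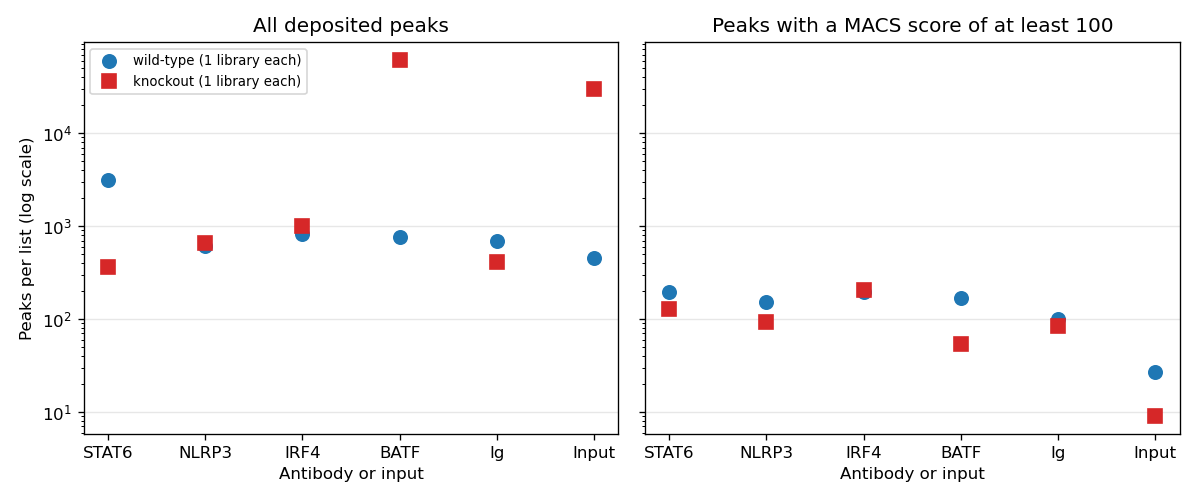
Number of peaks per list on a logarithmic axis for wild-type (circles) and knockout (squares) libraries, 1 library per point, for all deposited peaks (left) and for peaks with a score of at least 100 (right). The knockout BATF and input lists stand at 60926 and 30165 peaks on the left and at 54 and 9 peaks on the right, below their wild-type counterparts.

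The regions found in the most lists were shared by immunoprecipitated and background libraries. Of 97746 regions in any list, 139 appeared in at least 8 of the 12 lists, and 138 of these 139 were present in an Ig or input list. The latter count was largely fixed in advance, since with 8 ChIP lists a region in more than 8 lists must include a background list. Only the 26 regions in exactly 8 lists could have lacked one. The unplaced sequence Un_random held 52 of the 139. A total of 8 regions appeared in all 12 lists. The first of them, at chromosome 12 positions 3109828 to 3110154, had a score of at least 3100 in all 4 wild-type ChIP lists and in wild-type Ig, and scores of 1027 and 685 in wild-type and knockout input. The regions at chromosome 2 positions 98506357 to 98507522 and chromosome 9 positions 35112766 to 35113202 had a score of 3100 in every ChIP and Ig list. This was also the highest score of each of these lists except wild-type BATF, so equal scores of 3100 need not mean equal enrichment. In the input lists the chromosome 2 region scored 1544 in wild-type and 1368 in knockout, and the chromosome 9 region 735 and 407.

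The share of peaks also found in background libraries differed from list to list, for the same antibody too. The number of such peaks varied far less, from 134 in knockout NLRP3 to 183 in wild-type IRF4. List length ran from 361 to 60926 peaks, so the shares below mostly follow list length and do not rank the lists by background. In wild-type cells 29.1% (25.6 to 32.9) of NLRP3 peaks, 22.2% (19.4 to 25.2) of IRF4 peaks, 18.3% (15.6 to 21.2) of BATF peaks and 5.61% (4.83 to 6.48) of STAT6 peaks overlapped an Ig or input peak of the same genotype by at least 1 bp. In knockout cells the shares were 43.5% (38.3 to 48.8) for STAT6, 20.3% (17.3 to 23.5) for NLRP3, 16.2% (13.9 to 18.6) for IRF4 and 0.281% (0.240 to 0.326) for BATF. Random placement of the wild-type NLRP3 peaks within their chromosomes gave a mean of 0.304%, and that of the knockout BATF peaks 0.136%. With a minimum score of 100 in both lists the wild-type shares lay between 40.6% for BATF and 58.6% for NLRP3, and the knockout BATF share was 81.5%. Peaks that overlapped neither Ig nor input of their genotype are called control-free below. They numbered 2928 for STAT6, 433 for NLRP3, 641 for IRF4 and 631 for BATF in wild-type cells, and 204, 527, 845 and 60755 in knockout cells. Control-free peaks with a score of at least 100 were few: 65, 25, 50 and 87 in wild-type and 20, 7, 86 and 4 in knockout cells, in the same order of antibodies.

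The next comparison asks whether NLRP3 peaks lie at the peaks of the transcription factors. In wild-type cells 234 of 611 NLRP3 peaks, or 38.3% (34.4 to 42.3), overlapped an IRF4 peak, 33.9% (30.1 to 37.8) overlapped a STAT6 peak and 23.7% (20.4 to 27.3) overlapped a BATF peak. The Ig library, treated in the same way, had 27.1% (23.9 to 30.6) of its peaks in the IRF4 list, 26.4% (23.2 to 29.9) in STAT6 and 20.3% (17.4 to 23.5) in BATF. Most of the shared NLRP3 peaks were background regions. Of those shared with IRF4, 70.9% (64.7 to 76.7) also overlapped an Ig or input peak, and the shares were 74.9% (68.4 to 80.6) for STAT6 and 85.5% (78.7 to 90.8) for BATF. Among control-free peaks 66 of 433 NLRP3 peaks lay in the IRF4 list, which is 15.2% (11.99 to 18.98), with 11.3% (8.49 to 14.7) in STAT6 and 4.85% (3.03 to 7.32) in BATF. On chromosomes 1 to 19, X and Y alone the control-free shares were 11.99% (8.94 to 15.6) in IRF4, 7.40% (5.01 to 10.5) in STAT6 and 3.06% (1.59 to 5.29) in BATF, where random placement gave 0.00714%, 0.0255% and 0.00485%.

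The list of the NLRP3 antibody in the cells labelled as knockout was set beside it as background. It had 26.0% (22.7 to 29.5) of its peaks in knockout IRF4, 22.4% (19.3 to 25.8) in STAT6 and 16.6% (13.9 to 19.7) in BATF. Its control-free shares were 7.59% (5.48 to 10.2), 4.74% (3.09 to 6.92) and 3.80% (2.33 to 5.80). For control-free peaks the wild-type intervals lay above the knockout ones for IRF4 and STAT6, and for BATF they overlapped. On chromosomes 1 to 19, X and Y alone the knockout shares were 3.52% (2.06 to 5.58) in IRF4, 2.48% (1.29 to 4.30) in STAT6 and 2.90% (1.59 to 4.82) in BATF, where random placement gave 0.00725%, 0.00311% and 0.387%. The STAT6 lists searched differ in length, with 2928 wild-type and 204 knockout peaks. With a minimum score of 100 in both lists, control peaks included, the shares in IRF4 were 84.2% (77.4 to 89.6) in wild-type and 92.5% (85.1 to 96.9) in knockout cells, with overlapping intervals. Of control-free NLRP3 peaks 20.3% (16.6 to 24.4) in wild-type and 9.11% (6.79 to 11.9) in knockout cells met any of the 3 factors, and on chromosomes 1 to 19, X and Y alone 15.1% (11.7 to 18.98) and 4.97% (3.21 to 7.30) did. NLRP3 and Ig were also compared after both were filtered on the remaining 3 control lists. In wild-type cells 18.0% (14.6 to 21.9) of NLRP3 and 8.13% (5.97 to 10.8) of Ig peaks were then found in IRF4, 14.0% (10.9 to 17.6) and 7.58% (5.49 to 10.1) in STAT6, and 6.67% (4.54 to 9.38) and 4.07% (2.57 to 6.09) in BATF. In knockout cells 5.83% (3.96 to 8.21) of NLRP3 and 9.09% (5.97 to 13.1) of Ig peaks were found in IRF4. The knockout shares were 3.69% (2.24 to 5.70) and 7.64% (4.79 to 11.4) in STAT6, and 3.11% (1.79 to 4.996) and 4.73% (2.54 to 7.95) in BATF. The intervals of NLRP3 and Ig overlapped for all 3 factors in knockout cells. Of the control-free wild-type NLRP3 peaks, 8.78% (6.29 to 11.8) were also found in the knockout STAT6 list.

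**Figure D2:**
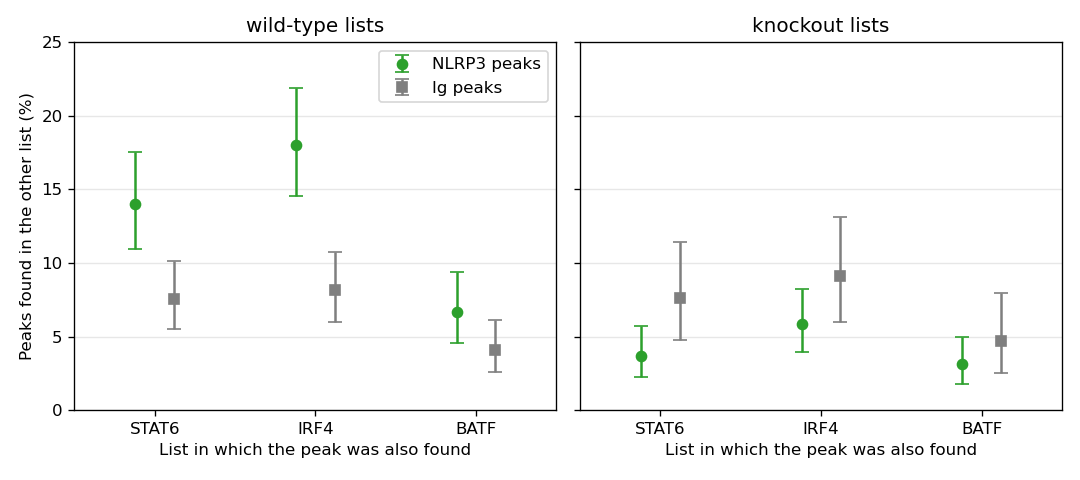
Share of NLRP3 peaks (circles) and Ig peaks (squares), in percent, also found in the STAT6, IRF4 and BATF lists of the same genotype, after both were filtered on the 3 other control lists. Bars are exact 95% intervals for counting error, with 1 library per point. In wild-type cells the NLRP3 share in IRF4 was 18.0% and the Ig share 8.13%, while in knockout cells they were 5.83% and 9.09%.

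The 5 highest-scored wild-type NLRP3 peaks outside every Ig and input list each met a wild-type factor peak. The region at chromosome 17 positions 71312978 to 71313140 scored 155 with NLRP3, 168 with wild-type IRF4 and 67.6 with knockout STAT6. The region at chromosome 19 positions 45724525 to 45724679 scored 154 with NLRP3, 81.3 with IRF4 and 76.8 with STAT6 in wild-type cells, and 97.1 with STAT6 and 51.9 with IRF4 in knockout cells. The region at chromosome 18 positions 3005627 to 3005977 scored 140.0 with NLRP3 and 172 with IRF4 in wild-type cells, and 120.3 with STAT6 and 79.1 with IRF4 in knockout cells. At chromosome 11 positions 53953528 to 53953802 NLRP3 scored 139.6 and IRF4 120.5 in wild-type cells, and knockout IRF4 scored 57.6. Knockout Ig had a peak within 1000 bp of this region. At chromosome X positions 37544313 to 37544387 NLRP3 scored 138 in wild-type and 79.7 in knockout cells, with wild-type STAT6 at 100.01, knockout IRF4 at 104.1 and knockout BATF at 56.7. This X-linked region was the only one of the 5 with a peak from the NLRP3 antibody in knockout cells, and all 5 had a peak in at least 1 knockout list.

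Whether a wild-type peak was also found in knockout cells depended on its score. Over all peaks 25.5% (22.5 to 28.6) of wild-type IRF4, 23.9% (20.6 to 27.5) of NLRP3, 19.4% (16.7 to 22.4) of BATF and 5.96% (5.16 to 6.86) of STAT6 peaks had a counterpart in the knockout list of the same antibody. For Ig the share was 20.03% (17.1 to 23.2), and for input 4.85% (3.06 to 7.24). Among control-free peaks the shares were 5.77% (4.10 to 7.87) for IRF4, 2.77% (1.44 to 4.79) for NLRP3, 8.72% (6.63 to 11.2) for BATF and 0.820% (0.526 to 1.22) for STAT6. Control-free wild-type peaks with a score of at least 100 were found in the knockout list more often than those scored 50 to under 75 for BATF, at 29.9% (20.5 to 40.6) against 4.19% (2.46 to 6.62). The corresponding values were 26.0% (14.6 to 40.3) against 3.85% (2.36 to 5.88) for IRF4 and 12.3% (5.47 to 22.8) against 0.431% (0.207 to 0.791) for STAT6. For NLRP3 the values were 8% (0.984 to 26.0), or 2 of 25 peaks, against 2.30% (0.998 to 4.48), and these intervals overlapped. Peaks with a score of at least 100 also recurred in knockout lists of other antibodies. Of the wild-type STAT6 ones 21.5% (12.3 to 33.5) were in knockout IRF4. Of the wild-type NLRP3 ones 44% (24.4 to 65.1) were in knockout STAT6 and 28% (12.1 to 49.4) in knockout IRF4. For BATF and IRF4 the knockout list of the same antibody held the largest share.

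**Figure D3:**
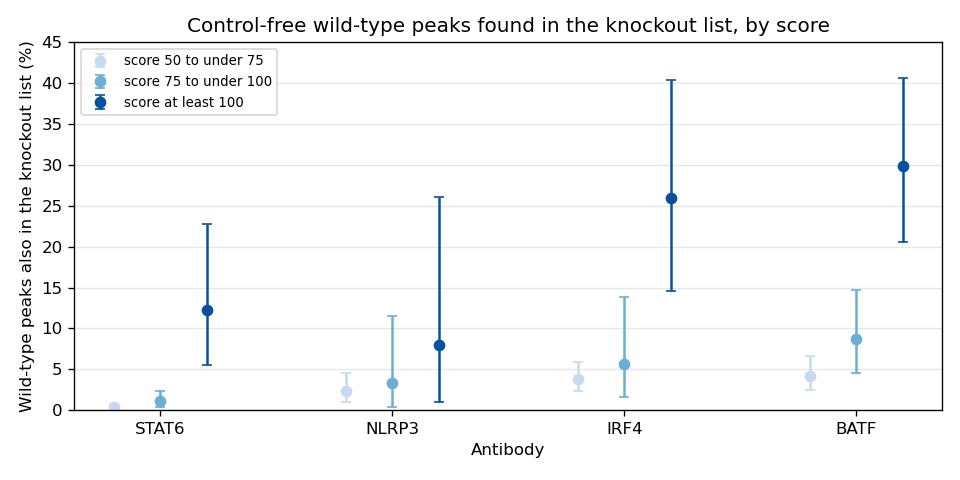
Share of control-free wild-type peaks, in percent, that overlapped a control-free peak of the knockout list of the same antibody, in 3 classes of the authors' score. Bars are exact 95% intervals for counting error, with 1 library per genotype. The share in the highest class was 29.9% for BATF, 26.0% for IRF4, 12.3% for STAT6 and 8% for NLRP3.

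The highest-scored wild-type BATF peaks outside every Ig and input list were found again in knockout BATF in 4 of 5 cases, at scores that are not comparable between lists. The wild-type BATF peak at chromosome 5 positions 114623079 to 114623200 scored 671 and had a peak of 90.4 in knockout BATF, and IRF4 scored 126 there in wild-type and 131 in knockout cells. Wild-type NLRP3 also had a peak of 118 at this site. The BATF peak at chromosome 5 positions 131995572 to 131995687 scored 500.3 in wild-type and 115 in knockout cells and was in no other list. At chromosome 9 positions 88448046 to 88448166 BATF scored 481 in wild-type and 90.4 in knockout cells, with wild-type IRF4 at 138 and NLRP3 at 82.9. The BATF peak at chromosome 7 positions 105208521 to 105208605 scored 376 in wild-type and 56.7 in knockout cells. The peak at chromosome 6 positions 131327529 to 131327645 scored 373 with BATF and 129 with IRF4 in wild-type cells and was in no knockout list. At chromosome 11 positions 25000059 to 25000204 BATF scored 356 in wild-type and 72.4 in knockout cells, with knockout IRF4 at 83.4. Of the 4 knockout BATF peaks that scored at least 100 and were control-free, 1 overlapped a wild-type BATF peak.

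IRF4 and BATF met at part of these sites. Of the 87 control-free wild-type BATF peaks with a score of at least 100, 16.1% (9.09 to 25.5) overlapped wild-type IRF4, 13.8% (7.34 to 22.9) knockout IRF4, 11.5% (5.65 to 20.1) wild-type STAT6, 9.20% (4.05 to 17.3) wild-type NLRP3, 2.30% (0.280 to 8.06) knockout NLRP3 and 1.15% (0.0291 to 6.24) knockout STAT6. Random placement gave 0.0103% for wild-type IRF4. Of the 50 control-free wild-type IRF4 peaks with such scores, 26 overlapped wild-type NLRP3, 20 wild-type STAT6 and 13 wild-type BATF, while 13 overlapped knockout IRF4, 10 knockout STAT6, 7 knockout BATF and 3 knockout NLRP3. The IRF4 peak at chromosome 13 positions 58869767 to 58869861 scored 194 in wild-type and 149 in knockout cells, with wild-type BATF at 284 and knockout BATF at 56.7. Of the control-free lists as a whole, 5.15% (3.57 to 7.15) of wild-type IRF4 peaks were in the BATF list and 8.42% (6.39 to 10.8) in the STAT6 list. In knockout cells 4.73% (3.40 to 6.39) of IRF4 peaks were in BATF and 5.09% (3.71 to 6.79) in STAT6. The control-free BATF lists searched held 631 wild-type and 60755 knockout peaks. Random placement of the IRF4 peaks gave 0.0192% in wild-type and 0.455% in knockout BATF, so the near-equal BATF shares are not alike relative to placement.

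STAT6 had the longest wild-type and the shortest knockout list, so only a small part of its wild-type peaks could be found again. Of all knockout STAT6 peaks 53.7% (48.4 to 59.0) were in the wild-type STAT6 list, against 23.0% (19.8 to 26.4) for NLRP3, 21.6% (19.1 to 24.3) for IRF4 and 0.248% (0.210 to 0.291) for BATF. These were 194, 152, 218 and 151 peaks, so the shares mostly follow the length of the knockout list. An equal share of knockout STAT6 peaks, 53.7%, lay in the knockout IRF4 list, so the value is not particular to STAT6. The highest-scored STAT6 region outside every Ig and input list, at chromosome 9 positions 23522173 to 23522265, scored 228 in wild-type STAT6 and had no peak in knockout STAT6. The same region had peaks of 134 with IRF4 and 111 with BATF in wild-type cells and of 234 with NLRP3 and 152 with IRF4 in knockout cells. Among peaks outside every Ig and input list it was also the highest-scored one of the NLRP3 antibody in knockout cells. The region at chromosome 9 positions 95326343 to 95326430 scored 159 with wild-type and 129 with knockout STAT6, and the region at chromosome 17 positions 63086877 to 63086970 scored 141 and 63.8. The region at chromosome 8 positions 73956979 to 73957078 scored 112 with wild-type STAT6, 101 with knockout STAT6 and 190.1 with knockout IRF4. The highest-scored knockout STAT6 region outside every Ig and input list, at chromosome 18 positions 82390366 to 82390763, scored 153 with STAT6 and had peaks in 6 lists. Read from the knockout side, 12.3% (8.09 to 17.6) of the 204 control-free knockout STAT6 peaks were in the wild-type STAT6 list and 18.1% (13.1 to 24.1) in the wild-type NLRP3 list. For the other antibodies the control-free knockout shares in their own wild-type list were 2.47% for NLRP3, 4.50% for IRF4 and 0.0905% for BATF.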

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

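The tests of explanations in this part were chosen after the results were seen.

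A pair of opposite differences in list length stands out, and neither was tested, with 1 library per group. From wild-type to knockout the number of BATF peaks was higher by 6.30 on the log2 scale and the number of STAT6 peaks lower, at -3.10, a difference of 9.41. The number of input peaks was higher by 6.05 and that of Ig peaks lower, at -0.74, a difference of 6.79. At a minimum score of 80 BATF (0.89) and STAT6 (-1.44) were still opposite and input (-0.36) and Ig (-0.32) were not. At a minimum of 100 neither pair was opposite, at -1.65 for BATF with -0.60 for STAT6, and -1.58 for input with -0.25 for Ig.

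The length of the knockout BATF list was set against 2 explanations. More BATF binding in knockout cells as the whole cause is argued against by the input, which had no antibody. Its knockout list was 66.4 times (60.6 to 73.1) as long as the wild-type one. Added binding would leave the earlier sites in place, and 8.72% (6.63 to 11.2) of control-free wild-type BATF peaks were found in the knockout BATF list. This share cannot decide the question, because recovery was low for every antibody, at 5.77% for IRF4, 2.77% for NLRP3 and 0.820% for STAT6. For BATF peaks with a score of at least 100 it was 29.9% (20.5 to 40.6). Peaks just past the caller's cut-off are in line with 87.9% of the knockout BATF peaks having a single score. The whole knockout BATF list met the knockout input list 80 times, where random placement gave 80.5. A shallow library, or a control library with few reads, may produce such a list, but neither the depth nor the control is known, and a smaller or relocated change in BATF binding stays open.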

How the results depend on the processing

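No paired analysis was possible because each group holds 1 library, and for the same reason leaving out a library in turn was not possible. The minimum scores of 80 and 200, the joint removal of control peaks and unplaced sequences from NLRP3 and Ig, and the shares of peaks with a score of at least 100 found in the knockout were chosen after seeing the data. The alternatives on promoter windows, gene windows and motifs were not run, for want of a genome and annotation of the build. The depth of the libraries is unknown, so its effect on the counts was not assessed, and the cause of the movements below was not tested.

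With a minimum score of 100 the lists in wild-type cells held 196 STAT6, 152 NLRP3, 195 IRF4, 170 BATF, 101 Ig and 27 input peaks, and those in knockout cells 129, 93, 203, 54, 85 and 9. The log2 ratio of knockout to wild-type counts then changed sign for NLRP3 (-0.71), BATF (-1.65) and input (-1.58). At a minimum of 80 it changed sign for NLRP3 (-0.40) and input (-0.36), and at 200 for NLRP3 (-0.53), BATF (-1.42) and input (-0.42). Without Ig and input peaks knockout STAT6 held 204 peaks, and the other 7 ChIP counts stayed within 1.5 times. All 12 counts stayed within 1.5 times when peaks within 1000 bp were merged, and when only chromosomes 1 to 19, X and Y were kept.

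With a minimum score of 100 in both lists, the percentages in Ig or input were 45.9 (STAT6), 58.6 (NLRP3), 49.2 (IRF4) and 40.6 (BATF) in wild-type cells and 58.1, 66.7, 39.9 and 81.5 in knockout cells. The percentages of wild-type peaks in the knockout list were then 50.5 for STAT6, 46.7 for NLRP3, 62.6 for IRF4, 28.8 for BATF, 69.3 for Ig and 29.6 for input. The percentages of NLRP3 peaks in STAT6, IRF4 and BATF were 73.7, 84.2 and 48.03 in wild-type and 80.6, 92.5 and 48.4 in knockout cells, with overlapping intervals between the genotypes for all 3 factors.

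On chromosomes 1 to 19, X and Y alone, the percentages in Ig or input were 3.33, 21.1, 15.4 and 11.8 for STAT6, NLRP3, IRF4 and BATF in wild-type cells and 34.5, 13.3, 10.8 and 0.217 in knockout cells. Those of wild-type peaks in the knockout list were 3.60 for STAT6, 15.9 for NLRP3, 16.7 for IRF4, 15.97 for BATF and 13.3 for Ig. NLRP3 peaks lay in STAT6, IRF4 and BATF at 23.5, 29.98 and 16.9 percent in wild-type and 14.2, 15.98 and 12.03 percent in knockout cells.

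Without Ig and input peaks, the percentages of wild-type peaks in the knockout list were 0.820 for STAT6, 2.77 for NLRP3, 5.77 for IRF4 and 8.72 for BATF, and those of NLRP3 peaks in STAT6, IRF4 and BATF were 11.3, 15.2 and 4.85 in wild-type and 4.74, 7.59 and 3.80 in knockout cells. With the unplaced sequences left out as well, the latter were 7.40, 11.99 and 3.06 in wild-type and 2.48, 3.52 and 2.90 in knockout cells. With equal filtering and without unplaced sequences, 14.25% (10.97 to 18.1) of wild-type NLRP3 and 5.31% (3.53 to 7.64) of wild-type Ig peaks were in IRF4. Within 1000 bp, the percentages in Ig or input were 6.48 for wild-type STAT6 and 51.5, 24.5, 22.2 and 2.58 for knockout STAT6, NLRP3, IRF4 and BATF. Those of wild-type peaks in the knockout list were 27.5 for NLRP3, 23.96 for BATF and 8.81 for input, and those of NLRP3 peaks in BATF were 27.3 in wild-type and 24.2 in knockout cells. An overlap of 50% of the shorter peak left 43 of the percentages within their intervals and moved that of knockout BATF in Ig or input to 0.220. With circular shifts in place of random placement, 43 ratios to chance stayed within the interval of the share divided by its mean placement share, and 1 did not. The shares of control-free peaks with a score of at least 100 found in the knockout stayed within their intervals for all 4 antibodies under an overlap of 50%, a distance of 1000 bp and chromosomes 1 to 19, X and Y alone.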

Other observations

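The tests of explanations in this part were all chosen after the results were seen. The Ig list as background for NLRP3 was planned, but not the equal filtering used here.

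Among regions outside every Ig and input list of either genotype, 66003 of 66287 were in a single ChIP list and 2 were in all 8. The knockout BATF list alone held 60735 such peaks, so the first count mostly describes that list. The region at chromosome 13 positions 74667246 to 74668108 had peaks with the 4 antibodies to named proteins in both genotypes, with scores of 189.6 for IRF4 and 82.5 for NLRP3 in wild-type cells and of 186 for STAT6, 153 for IRF4 and 68.7 for NLRP3 in knockout cells, and both Ig lists had a peak within 1000 bp of it. The highest-scored wild-type IRF4 peak of these regions lay at chromosome 17 positions 39979917 to 39985757 and scored 432. The only other list with a peak there was wild-type STAT6, at 59.4. This IRF4 peak spanned 5841 bp, where the median width of control-free wild-type IRF4 peaks was 153 bp. Whether so wide a peak reflects IRF4 binding was not tested. Among the highest knockout NLRP3 peaks, those at chromosome 12 positions 51709393 to 51709456 (123), chromosome 1 positions 55667149 to 55667212 (99.2) and chromosome 1 positions 164198765 to 164198830 (99.2) were in no other list.

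Wild-type NLRP3 and IRF4 peaks coincided at 234 NLRP3 peaks, and regions that gather reads in every library are in line with 70.9% of these, which were also Ig or input peaks. The same background as in the Ig library cannot be told apart from another cause for the rest, because with equal filtering 8.1% of Ig peaks against 18.0% of NLRP3 peaks were in IRF4, but the ratios to random placement, 222 and 257 times with all sequences and 871 and 1839 on chromosomes 1 to 19, X and Y, depend on the sequences kept and in the latter case on a mean of 0.031 chance overlaps. Sharing between libraries with peaks of like width stays open too, since 18.1% of control-free knockout STAT6 peaks against 10.3% of wild-type IRF4 peaks lay in wild-type NLRP3, but 8.78% of wild-type NLRP3 peaks lay in knockout STAT6 against 15.2% in wild-type IRF4. Of the 66 control-free NLRP3 peaks shared with IRF4, 9.1% (3.41 to 18.7) recurred with the NLRP3 antibody in knockout cells, 30.3% (19.6 to 42.9) with IRF4 and 36.4% (24.9 to 49.1) with STAT6, against 1.63%, 3.27% and 3.81% of the 367 without an IRF4 peak. Part of these regions was thus recovered in knockout libraries, and binding that depends on NLRP3 at the others stays open, as 1 library per genotype does not decide it.

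The knockout BATF and knockout input lists differed on the sex chromosomes, where the ratio of BATF to input peaks departed from the autosomes: it lay between 1.83 and 2.15 on the 19 autosomes, at 3.57 (3.33 to 3.83) on X and at 1.24 (1.09 to 1.43) on the unplaced Y sequence, while the unplaced Un_random sequence, with 32 input peaks, also lay high at 3.38 (2.26 to 5.18). The wild-type input had 6.3% (4.202 to 8.93) of its autosomal and X peaks on X. This was near the 5.98% (5.80 to 6.18) of knockout BATF and above the 3.40% (3.20 to 3.61) of knockout input. The wild-type input came from other cells, also of unknown sex, so it is no baseline for the knockout libraries. BATF enrichment on X as the cause therefore stays open. The opposite shift on the unplaced Y sequence is what different proportions of male and female cells in these 2 knockout libraries would give. That hypothesis is not settled by the labels, which give no sex, and the ratio on the assembled Y chromosome was not computed. Of the shorter knockout lists, NLRP3 had 3.79% (2.36 to 5.74) of its autosomal and X peaks on X, below the knockout BATF value, IRF4 6.11% (4.61 to 7.92) and STAT6 6.61% (3.90 to 10.4), above the knockout input value, and Ig 3.93% (2.11 to 6.62), apart from neither. On the unplaced Y sequence lay 1.97% (1.05 to 3.34) of NLRP3, 1.21% (0.394 to 2.80) of Ig, 0.794% (0.343 to 1.56) of IRF4 and none of the STAT6 peaks, against 0.776% (0.708 to 0.849) for knockout BATF and 1.26% (1.14 to 1.39) for knockout input. Of the wild-type lists only STAT6 had peaks on this unplaced sequence, at 0.355% (0.177 to 0.634). Peaks on the assembled Y chromosome are not in these shares, and the wild-type STAT6, NLRP3, IRF4 and Ig lists were not free of them. The knockout intervals lay above the wild-type ones for NLRP3, BATF and input, and overlapped them for STAT6, IRF4 and Ig. A difference in sex between the genotypes was not tested, and it would bear on every comparison of wild-type with knockout.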
